A study of Caenorhabditis elegans with 2 samples.

How the data were processed

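Whole L4 larvae of a strain with nhr-41 tagged in place with TY1, eGFP and 3xFLAG were processed as 2 biological replicates of 1 group, per the labels. The animals were synchronised as starved L1 larvae after bleaching and collected at 48.5 h. Chromatin was sheared by sonication to fragments of 200 to 800 bp and precipitated with an antibody against GFP, per the labels. The starting points here were 8 peak lists on the genome build ce11 that the authors deposited. These are a ranked and a thresholded list for each replicate, and 2 ranked, 1 thresholded and 1 conservative thresholded list made from both replicates. Peaks were ranked by the irreproducible discovery rate (IDR), which measures how stable a peak's rank is between peak sets. Per the submitters' notes, each list was derived from the replicates' alignments and a control alignment, and the thresholded lists also from a further file whose role is not stated there. The aligner, the peak caller and their versions are not given in the sources used here.

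The score of each peak was deposited by the authors as an IDR score capped at 1000, and the lowest score in every thresholded list was 830. The signal of each peak is the value the authors' peak caller gave, and what it is relative to is not given in the sources used here. Signal and score were used to describe, rank or filter peaks within a list. All 1069 conservative peaks stood in a ranked list of both replicates with the same coordinates, score and signal, so peaks absent from the conservative list were compared with them inside that ranked list. It also gave the signal of the overlapping peak in each of 2 peak sets, and these signals were correlated across peaks. Their columns carry no replicate number, so they entered as an unnumbered replicate mean ± SD with n = 2. A further 6 columns of such signals, in ranked lists of other peak sets, were not used. The list of replicate 1 held 347 peaks, that of replicate 2 held 676, the conservative list 1069 and the other thresholded list 1136, of which 906 had the same coordinates as a conservative peak. In the conservative list 102 peaks formed 51 sets that shared the same pair of replicate peaks. Read depth was unknown, so no value carries a depth limit.

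The conservative list was used for all results unless another is named. Coordinates were set on the RefSeq sequence of the assembly WBcel235, the same as ce11, with gene models of Ensembl release 115, and 0 peaks lay outside the ends of its chromosomes. A summit was placed in the class promoter, 5' UTR, coding exon, 3' UTR, intron or intergenic, in this order of priority. A promoter ran from 1000 bp upstream to 200 bp downstream of a transcript start of a protein-coding gene, and a gene with a summit there was called bound. Observed shares were compared with 10000 circular shifts of all summits along their chromosomes (2-sided permutation test, smallest p 0.0002), and tRNA genes without an identical copy with 1000 shifts. Overlap between replicates needed 1 bp. Chromosome shares were tested with the exact binomial test against length, 39 gene lists with Fisher's exact test against all 19973 protein-coding genes, and 26 motifs and 2080 6-mers with the exact McNemar test. Windows reached 75 bp to each side of the summit, with control windows centred 500 bp away on a side drawn at random with a fixed seed. Direct and inverted repeats were matched with up to 2 mismatches, and the POU site and the B box with up to 1. GC-matched windows came from promoters of unbound genes, within 2 percentage points of GC. Benjamini-Hochberg adjustment was applied within each family, with a threshold of 0.05. Rank correlations used 100000 permutations. Binomial intervals are exact (Clopper-Pearson) at 95% and, like the counts, cover counting error only.

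The gene lists, the motifs, the tests and most alternatives were chosen before the data were examined. Named genes were nhr-41, the genes at the 20 promoter peaks with the highest signal, and up to 4 bound members with the highest signal of each list past its test. For motifs, every one past its test and the 5 6-mers with the smallest p were named. Further genes are said to have been chosen after their values were seen. Alternatives were the other thresholded list, each replicate's own list, promoters of 500 and 2000 bp, other overlap rules, windows of 50 and 100 bp, other backgrounds and matched GC content. A stricter score of 1000, 1 peak per pair of replicate peaks, and lists without peaks near tRNA genes or near tRNA, snRNA and snoRNA genes were added after the data had been seen, as was the comparison of chromosome shares with ranked peaks under the threshold. The planned stricter score of 830 was the lists' own minimum and removed no peak.

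The procedures were tested on simulated data. With random summits the promoter class was called in 0 of 20 sets, and with 30% of summits moved into promoters in 20 of 20. With random bound genes any gene list was called in 3 of 100 sets, and ribosomal protein genes drawn 6 times as often were called in 81 of 100. With random windows 0 fixed motifs and 1 6-mer were called over 5 sets, and a half-site written into 8% of the summit windows was called in 5 of 5. The simulated windows lay at random positions, whereas real summits had 46.4% GC against 35.6% in flanks. The simulated genes were drawn independently, whereas 97 real peaks were assigned to 2 or more genes. The false call rates for motifs, 6-mers and gene lists do not cover these differences. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads and control samples were not analysed here.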

Results

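NHR-41, a Caenorhabditis elegans nuclear receptor related to the vertebrate TR2 and TR4 receptors, was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in L4 larvae, the last larval stage before adulthood. The animals carried an enhanced green fluorescent protein (eGFP) tag at the endogenous nhr-41 gene, were collected at 48.5 h, and the tagged protein was recovered with an antibody against GFP. There was 1 group of 2 biological replicates. The comparisons were therefore replicate against replicate, and bound positions against positions elsewhere in the genome. The conservative list, made by the authors from both replicates, held 1069 peaks with a median signal value of 82.8 and a highest value of 318. The list of replicate 1 alone held 347 peaks and that of replicate 2 alone held 676, a ratio of 1.95. Read depth was unknown, because the peak lists carry no read totals.

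The replicates shared most of the sites of the smaller list. Of the 347 replicate 1 peaks, 251 were overlapped by a replicate 2 peak, which is 72.3% (95% interval 67.3 to 77.0). Of the 676 replicate 2 peaks, 250 were overlapped by a replicate 1 peak, which is 37.0% (33.3 to 40.7). Circular shifts of the peaks along each chromosome gave an overlap of 0.369% and 0.189% in these directions, and the 2-sided permutation p was 0.0002 for both, the smallest that 10000 shifts can give. The conservative list overlapped 92.2% of the replicate 1 peaks and 80.8% of the replicate 2 peaks. Across the 1069 conservative peaks the signals of the replicates had a Pearson r of 0.627 and a Spearman rho of 0.314. Across all 48276 peaks ranked in both, r was 0.640 and rho was 0.232, each with a permutation p of 1e-05, the smallest possible. With 1 peak per pair of replicate peaks, which left 41154, r was 0.656 and rho was 0.239. The 48276 peaks include 1 at X 15811049 to 15811139, absent from the conservative list, with replicate signals of 993 and 826. How far that peak raised r was not examined. These correlations are across peaks, which are not independent replicates. The signal of 1 replicate, unnumbered in the list, was higher than that of the other at 822 of the 1069 peaks (76.9%), with medians of 46.9 and 36.7, and each SD of replicate signals includes this offset.

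The strongest peak of the conservative list, at III 3867491 to 3867651 (all coordinates are 1-based, genome build ce11), lay upstream of rpl-3, which encodes a protein of the large ribosomal subunit. Its summit was 283 bp before a transcript start, its signal was 318, and the mean of its replicate signals was 155 ± 22.0 (SD, n = 2). A peak at III 4899849 to 4899980 with a signal of 244 (replicate mean 119.5 ± 7.66, SD, n = 2) lay upstream of nhl-2, a TRIM-NHL protein that acts with microRNAs, and of tag-340. The promoters of myrf-1, a membrane-bound transcription factor needed for moulting, and hlh-30, the TFEB orthologue that controls autophagy genes, carried signals of 218 and 194, with replicate means of 106 ± 20.5 and 97.7 ± 13.9 (SD, n = 2). The divergent Hsp70 genes F44E5.4 and F44E5.5 shared a peak of 219.5 at II 11759328 to 11759611. Among the 20 strongest promoter peaks, which were assigned to 27 genes, were further those of rpl-35 (220.4), rpl-15 with K11H12.8 (189), and rpl-20 with Y17G9B.5 (176). The others with a known role lay at tasp-1 with K01G5.10 (224), mog-4 (198), cdc-48.1 (173), sec-61.G with F32D8.13 (173), hsp-3 (170.5), kvs-3 (167) and egg-5 (167). The remaining promoters of the 20 were those of serp-1.1 (215), madf-9 (212), F42G4.5 (203), H41C03.3 (189) and the pair F55A11.11 and F55A11.6 (168). The kvs-3 summit lay within 500 bp of a tRNA gene. The summits at H41C03.3, cdc-48.1, F55A11.11 and egg-5 lay within 500 bp of an snRNA or snoRNA gene.

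With promoters of 1000 bp upstream, promoters held the largest share of NHR-41 summits among the region classes. Of the 1069 summits, 462 lay in a promoter window, from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, which is 43.2% (95% interval 40.2 to 46.2) against 25.8% after circular shifts. Intergenic sequence held 30.9% against 25.5%. Introns held 22.7% against 27.3%, coding exons 2.15% against 18.7%, and 3' UTRs 0.748% against 2.41%. The promoter, coding exon and 3' UTR shares had a permutation p of 0.0002, the smallest possible before adjustment, and an adjusted permutation p of 0.0004. The adjusted permutation p was 0.0006 for intergenic sequence and 0.00336 for introns. The 3 summits in 5' UTRs (0.281% against 0.418%) did not differ from the shifts, with an adjusted p of 0.702. Classes were set by protein-coding genes alone, so a summit at a tRNA gene could count as intergenic or intronic. Among the 850 summits not within 500 bp of a tRNA gene, promoters held 47.8% against 26.2% after shifts. Intergenic sequence held 29.3% of these against 24.9%, and introns 19.2% against 27.3%. Ranked peaks under the authors' threshold lay in promoters in 29.0% of 47168 cases, less often than the conservative peaks (odds ratio 1.87, Fisher's exact p = 1.56e-22). With a promoter of 500 bp upstream the share at promoters was 31.8%, and it stayed above the shifted share. Whether promoters were still the largest class at that setting was not examined.

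**Figure D1:**
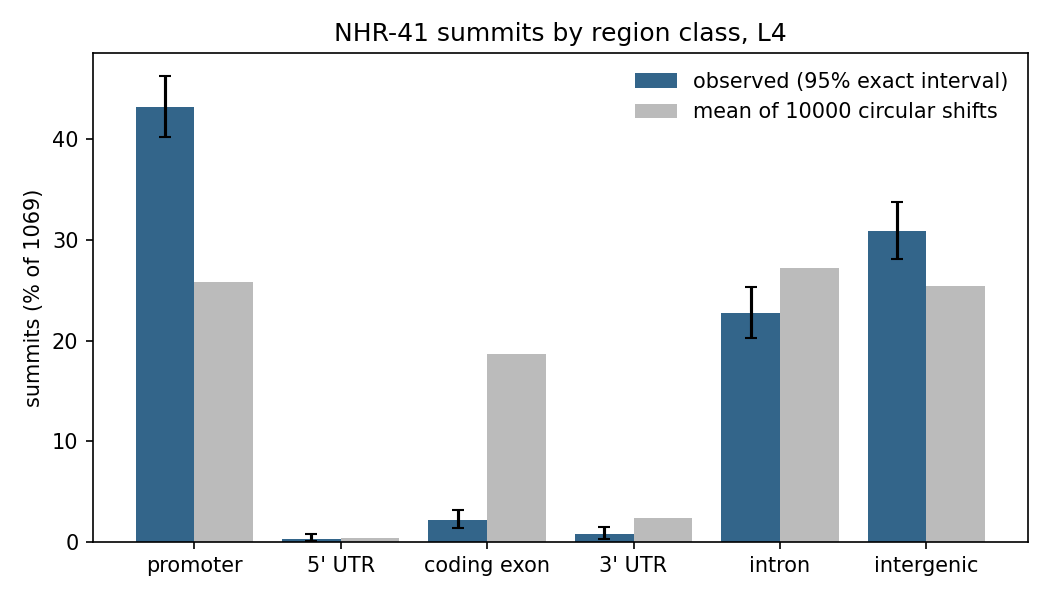
Share of the 1069 NHR-41 summits in each region class (vertical axis, percent; dark bars, with 95% exact binomial intervals) beside the mean of 10000 circular shifts (grey bars). Promoters held 43.2% against 25.8%, and coding exons 2.15% against 18.7%.

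Genes for small structural RNAs were the most over-represented features. A summit lay within 500 bp of a tRNA gene at 219 of 1069 peaks, 20.5% (95% interval 18.1 to 23.0) against 0.632% after shifts, a 32.4-fold difference. The share was 6.74% near snoRNA genes, which guide RNA modification (17.9-fold), with 11.2% in the list of replicate 1 alone, and 1.68% near snRNA genes (13.7-fold). It was 30.5% near genes annotated as ncRNA (4.32-fold). A summit could count in more than 1 class, since some ncRNA genes lie at or beside a tRNA, snRNA or snoRNA gene. The ncRNA share was not tested without summits near those genes. These 4 classes had a permutation p of 0.0002, the smallest possible before adjustment, and an adjusted permutation p of 0.00045. Only 8 summits lay near miRNA genes (0.748%, 2.81-fold, adjusted permutation p = 0.0403), against 1.44% in the list of replicate 1 alone, and summits near piRNA genes were fewer than after shifts (2.90% against 4.50%, adjusted permutation p = 0.0471). Both of these calls were lost in the replicate 2 list alone (adjusted permutation p = 0.278 and 0.0846), and the piRNA call in the replicate 1 list (adjusted permutation p = 0.196). Each was lost in 5 of the 6 alternatives that changed the peaks or the distance. No summit of the conservative list lay near any of the 20 rRNA genes, where the shifts gave 0.0211%, too few for a deficit to be seen. Ranked peaks at V 17128074 to 17128357 (signal 96.0) and V 17122079 to 17122362 (95.4) each lay within 500 bp of an rRNA gene. Both had a score of 1000 and were absent from the conservative list, so the absence there does not show a lack of signal.

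Of the 612 tRNA genes, 257 had a summit within 500 bp (42.0%, 95% interval 38.0 to 46.0) and 152 had a summit inside the gene. On the X chromosome 134 of 276 tRNA genes had a summit within 500 bp (48.6%), against 123 of 336 on the autosomes (36.6%, odds ratio 1.63, Fisher's exact p = 0.00308). Neighbouring tRNA genes can share a summit, so the genes in this test were not independent. A summit lay inside the gene at 28.6% of tRNA genes on X and 21.7% on the autosomes, a difference that was not tested. The peaks near tRNA genes had a median signal of 85.9 and the others of 81.6. The following examples were chosen after their values were seen. A peak of 247 at X 3036106 to 3036230 had its summit inside a tRNA gene. A peak of 311 (replicate mean 158 ± 26.8, SD, n = 2) lay in an intron of pxn-1 beside the snoRNA gene ZK994.7, and a peak of 264 in an intron of frm-7 at the snoRNA genes C51F7.3 and C51F7.4. The gene rpr-1, the RNA component of RNase P, which trims tRNA precursors, carried a peak of 234 in an intron of ints-8. No peak list from an untagged or input control was used here, so sites shared with other immunoprecipitations were not separated.

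**Figure D2:**
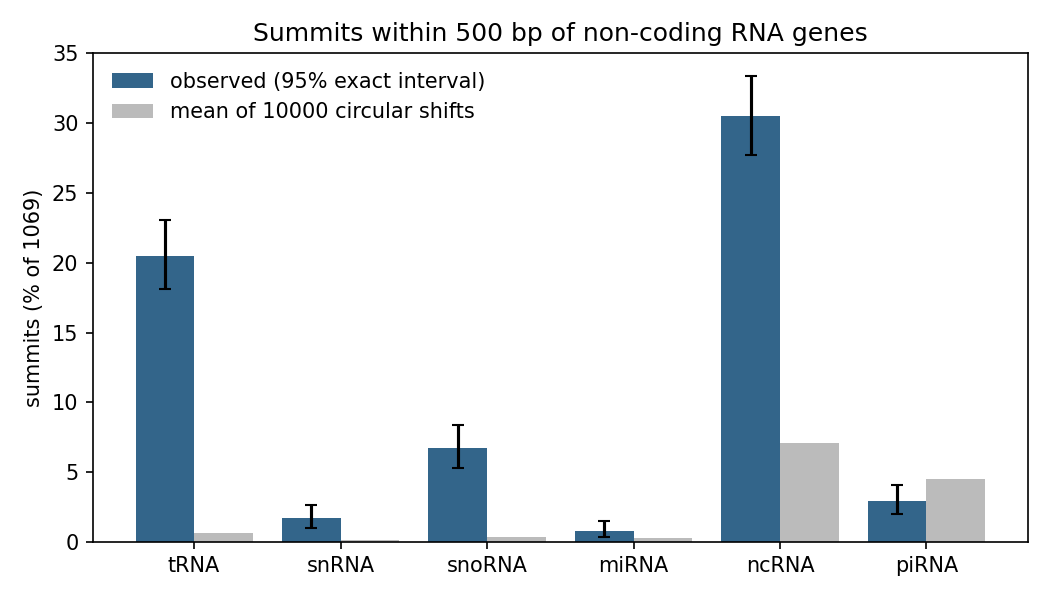
Share of the 1069 summits within 500 bp of genes of 6 non-coding classes (vertical axis, percent; dark bars, with 95% exact binomial intervals) beside the mean of 10000 circular shifts (grey bars). Near tRNA genes the share was 20.5% against 0.632%.

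The X chromosome carried more peaks than its length gives, and chromosome V fewer. X held 255 peaks, 23.9% (95% interval 21.3 to 26.5) against 17.7% of the genome's length (exact binomial test, adjusted exact p = 9.9e-07). Chromosome V held 154 peaks, 14.4% against 20.9% (adjusted exact p = 4.08e-07). The shares on I, II, III and IV were 13.9%, 17.7%, 14.2% and 15.9%, with adjusted exact p values of 0.416, 0.0597, 0.657 and 0.296. Without the peaks near tRNA genes, X held 146 of 850 peaks, 17.2% (14.7 to 19.9), and its call ended (adjusted exact p = 0.904). The deficit on V stayed at 15.8% (adjusted exact p = 0.000595), and chromosome II, with 20.1% against 15.2% of the length, passed the test at the same adjusted exact p. The middle 50% of the chromosomes held 59.6% of the peaks (56.6 to 62.5, exact binomial p = 3.9e-10). This share was 72.7% on V, 66.4% on I and 65.1% on II, against 51.2% on IV and 49.0% on X.

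**Figure D3:**
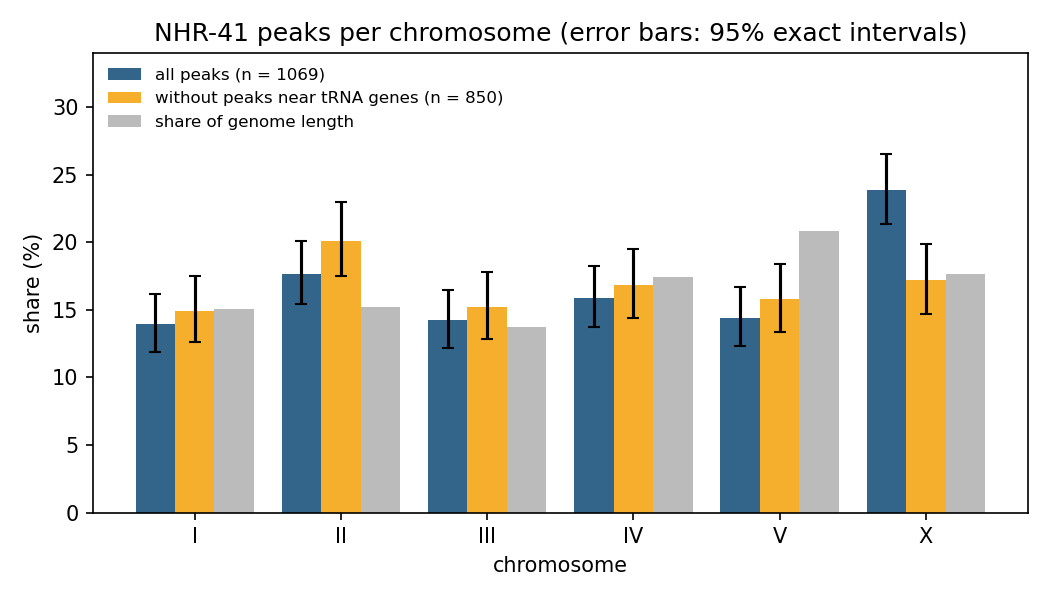
Share of peaks on each chromosome (vertical axis, percent, with 95% exact binomial intervals) for all 1069 peaks (dark bars) and for the 850 peaks not near a tRNA gene (orange bars), beside the chromosome's share of the genome's length (grey bars). X fell from 23.9% to 17.2% when the peaks near tRNA genes were left out.

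A summit lay in the promoter window of 535 of 19973 protein-coding genes, 2.68%. Of 39 fixed gene lists, 5 were bound more often than other genes and 2 less often (Fisher's exact test, 2-sided, Benjamini-Hochberg adjustment). No control peak list was used here, so peaks at these genes were not separated from sites shared with other immunoprecipitations. Ribosomal protein genes were bound at 12 of 81 members (odds ratio 6.44, adjusted exact p = 3.1e-05), with rpl-3 (318), rpl-35 (220.4), rpl-15 (189) and rpl-20 (176) carrying the highest signals. The odds ratio of this list was 19.02 in the peaks of replicate 1 alone and 2.65 with the nearest transcript start. Respiratory chain genes were bound at 7 of 49 (odds ratio 6.12, adjusted exact p = 0.00401), among them the cytochrome c oxidase genes cox-5A (130.3), cox-5B (111) and cox-6A (89.0) and the succinate dehydrogenase gene sdha-1 (72.1). The cox-6A and sdha-1 summits lay within 500 bp of an snRNA or snoRNA gene. Heat shock protein genes were bound at 7 of 53 (odds ratio 5.59, adjusted exact p = 0.00492). Among them were hsp-3, the BiP chaperone of the endoplasmic reticulum (170.5), dnj-13 (143), hsp-1 (108) and hsp-90 (91.3). The odds ratio of this list was 9.48 in the peaks of replicate 1 alone. Lists were matched by gene name, and this one did not hold the Hsp70 genes F44E5.4 and F44E5.5, which shared a stronger peak (219.5). Heterochronic genes, which time larval development, were bound at 4 of 17 (odds ratio 11.3, adjusted exact p = 0.00716): nhl-2 (244), the Pumilio-family gene puf-9 (164), lin-66 (85.4) and mab-10, a cofactor of LIN-29 (57.6). Translation factor genes were bound at 5 of 42 (odds ratio 4.95, adjusted exact p = 0.0283), with iff-2 (143), pab-2 (101), eef-1A.2 (93.0) and eef-2 (93.0).

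Chemoreceptor genes, which are expressed in few sensory neurons, seldom had an NHR-41 summit in the promoter window, with 2 of 1310 bound (odds ratio 0.0520, adjusted exact p = 5.42e-12). The odds ratio was 0.164 in the peaks of replicate 1 alone, 0.196 in those of replicate 2 alone and 0.161 with 2000 bp promoters. These were sre-23 (135) and srh-269 (107), and both summits lay within 500 bp of a small structural RNA gene. F-box and MATH-BTB genes were bound at 2 of 395 (odds ratio 0.182, adjusted exact p = 0.0163), at fbxb-58 (127) and fbxc-29 (112). Other lists did not pass the test. Nuclear hormone receptor genes were bound at 7 of 274, intestine genes at 3 of 50, body wall muscle genes at 1 of 41, germline genes at 1 of 60, cuticle collagens at 2 of 176, and pan-neuronal genes at 0 of 35. With circular shifts in place of Fisher's exact test, which keep promoter length and neighbours, the calls for chemoreceptors and ribosomal proteins held (adjusted permutation p = 0.0117 for both). The other 5 did not, with adjusted permutation p values of 0.0702 for the respiratory chain, 0.146 for heat shock proteins, 0.333 for heterochronic genes and for translation factors, and 0.441 for F-box and MATH-BTB genes. Their ratios to the shifted share were 5.90, 4.64, 3.85, 4.16 and 0.214, in the order respiratory chain, heat shock, heterochronic, translation factor and F-box. In the shorter list of replicate 1 alone, the calls for the respiratory chain and heterochronic genes (adjusted exact p = 0.0735 for both), F-box and MATH-BTB genes (0.868) and translation factors (0.288) were lost, at odds ratios of 7.53, 15.3, 0.285 and 5.74. In that of replicate 2 alone, those for heterochronic genes and translation factors (adjusted exact p = 0.196 for both) and F-box and MATH-BTB genes (0.230) were lost, at odds ratios of 7.26, 4.19 and 0.272. When each peak was given to the nearest transcript start, the calls for ribosomal proteins, heat shock proteins and translation factors (adjusted exact p = 0.0540 for each) and the respiratory chain (0.0893) were lost. Their odds ratios were 2.65, 3.22, 3.53 and 2.95 in that order. At a score of 1000, which left 781 peaks, the calls for the respiratory chain (adjusted exact p = 0.0832), translation factors (0.0570) and F-box and MATH-BTB genes (0.191) were lost. Their odds ratios were 4.52, 5.36 and 0.253. With genes holding a ranked peak as background, those for heterochronic genes (adjusted exact p = 0.0744), translation factors (0.179) and F-box and MATH-BTB genes (0.0813) were lost, at odds ratios of 5.79, 3.10 and 0.221. The translation factor and F-box calls were also lost without peaks near tRNA, snRNA or snoRNA genes (adjusted exact p = 0.0678 for both). Their odds ratios there were 4.75 and 0.224, near the 4.95 and 0.182 of the full list. The F-box call was lost in the other thresholded list too (adjusted exact p = 0.126, odds ratio 0.351).

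**Figure D4:**
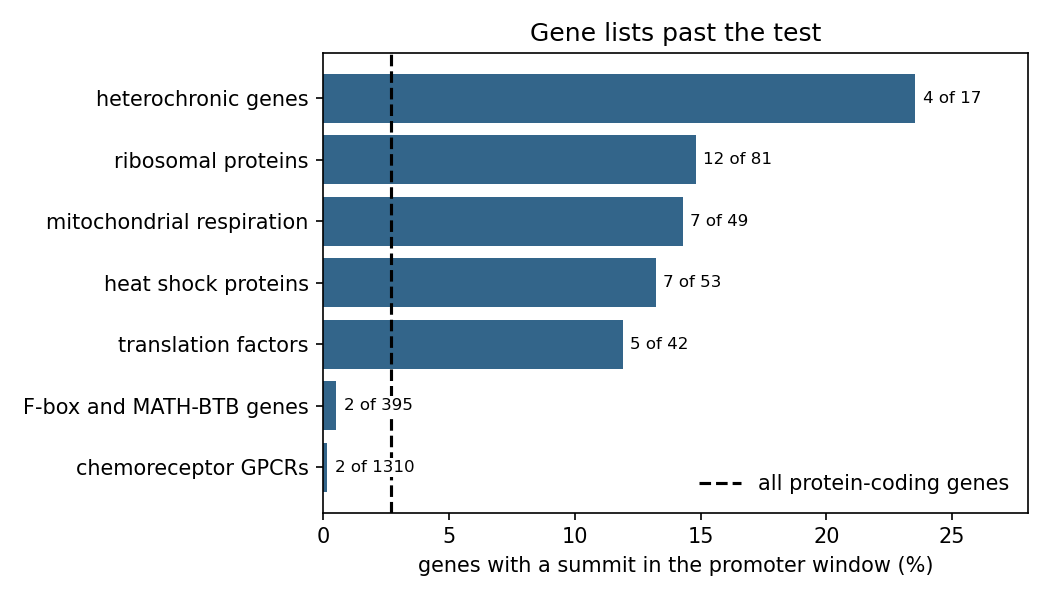
Percent of the genes of each list with an NHR-41 summit in the promoter window (horizontal axis), for the 7 lists past Fisher's exact test, with bound and total members beside each bar. The dashed line is the share over all protein-coding genes, 2.68%.

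Sequences known to bind nuclear receptors were among the motifs found more often at summits. The half-site AGGTCA, the core that TR2-type receptors recognise, lay within 75 bp of 10.2% of the 1069 summits and in 4.68% of equal windows centred 500 bp away (exact McNemar test, adjusted exact p = 6.56e-06). The extended form AAGGTCA was present in 4.12% against 1.68% (adjusted exact p = 0.00281). The GATA factor site TGATAA was present in 22.7% against 15.4% (adjusted exact p = 5.98e-05). The internal promoter elements of tRNA genes stood out most, with the B box in 17.3% against 1.22% and the A box in 5.80% against 0.374% (adjusted exact p = 4.61e-42 and 2.71e-13). Without peaks near tRNA genes the B box was present at 3.88% and the A box at 1.65% of summits, and without those near tRNA, snRNA or snoRNA genes the B box at 2.49% (adjusted exact p = 0.0113) and the A box at 1.05%. GAGA repeats (5.71% against 1.50%), the Sp1 site GGGCGG (8.79% against 2.62%), the E-box CACGTG (6.64% against 2.62%) and the E2F site (5.33% against 2.15%) were also more frequent, with adjusted exact p values of 4.39e-07, 1.01e-09, 2.39e-05 and 0.000476. The homeobox site TAATTA (2.34% against 9.35%), the POU site (14.8% against 24.0%) and the TATA box (3.65% against 7.20%) were less frequent, with adjusted exact p values of 2.81e-11, 1.66e-07 and 0.00077. The direct repeats of the half-site with spacers of 0 to 5 bp and the inverted repeat did not pass the test. The nearest was the repeat with a 2 bp spacer, in 2.15% against 0.935% (adjusted exact p = 0.0702).

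Summit windows were richer in GC than the flanks, at 46.4% against 35.6%. Against windows of matched GC content from promoters of unbound genes, 6 of the 12 motifs kept the call: the half-site (4.86% of matched windows, adjusted exact p = 2.35e-05), AAGGTCA, TGATAA (8.23%, adjusted exact p = 1.04e-19), the GAGA repeat and both tRNA gene boxes. The Sp1 site was as frequent in matched windows as at summits, at 8.79% in each, and the POU site turned direction, at 14.8% of summits against 14.4% of matched windows (adjusted exact p = 0.966). The calls for CACGTG, E2F, TAATTA and the TATA box were lost there (adjusted exact p = 0.452, 0.0966, 0.469 and 0.391). In the 347 peaks of replicate 1 alone, the calls for TGATAA, CACGTG and E2F (adjusted exact p = 0.431, 0.794 and 0.431), AAGGTCA (0.207), the TATA box (0.107) and the POU site (0.380) were lost. Their shares at these summits were 17.6%, 5.19%, 5.76%, 4.03%, 3.75% and 17.0% in that order, and TAATTA was present at 0.865%. The AAGGTCA call was also lost with windows of 50 bp (adjusted exact p = 0.0773), and the A box call without peaks near tRNA, snRNA or snoRNA genes (0.167). Of 2080 6-mers pooled with their reverse complements, 636 were more and 371 less frequent at summits. The 5 with the smallest p, AAAAAT (31.2% against 60.6%), AAAATT (25.4% against 53.8%), ATTTTA, TAAAAA and TTAAAA, were all less frequent, and all 5 calls were lost against matched windows. There 250 6-mers were more and 237 less frequent, and TGATAA had the smallest p.

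**Figure D5:**
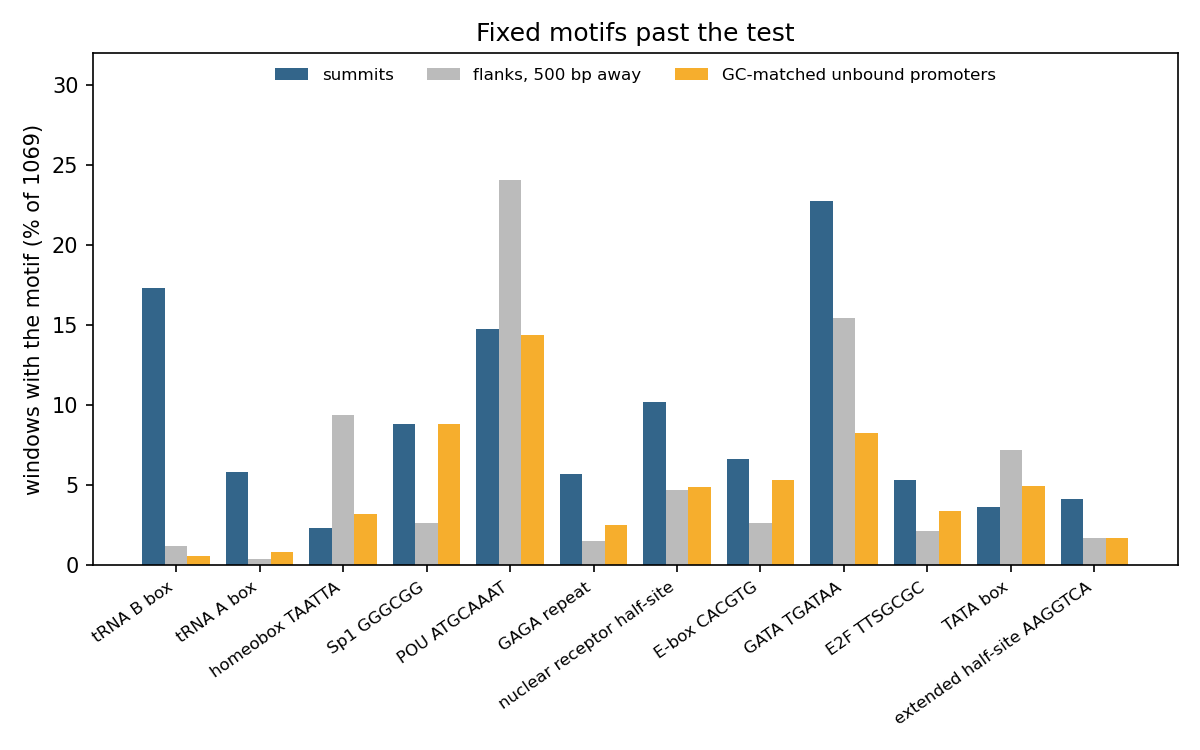
Percent of windows with each of the 12 fixed motifs past the test (vertical axis) at the 1069 summits (dark bars), in flanks centred 500 bp away (grey bars) and in GC-matched windows of unbound promoters (orange bars). The half-site was present in 10.2%, 4.68% and 4.86%, and the Sp1 site in 8.79%, 2.62% and 8.79%.

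The nhr-41 gene itself (WBGene00022423, IV 1386215 to 1399353, plus strand) carried 2 conservative peaks. The peak at IV 1388086 to 1388369 had a signal of 94.0 (replicate mean 50.5 ± 0.407, SD, n = 2) and a summit 131 bp downstream of one of the gene's transcript starts. That summit also lay inside a tRNA gene on the opposite strand, at IV 1388216 to 1388287. The peak at IV 1389635 to 1389918 lay in an intron, with a signal of 89.2 and replicate signals of 23.5 and 65.0. The list of replicate 2 held both peaks, and that of replicate 1 only the one at the tRNA gene. The fifth strongest peak of the conservative list, with a signal of 257 at IV 1379074 to 1379222, was intergenic, with its summit 7068 bp upstream of the gene's first transcript start. It lay outside the window of 5000 bp fixed for this gene and is named after its value was seen.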

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

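No test was planned for these peaks, which were singled out after the ranked list had been seen. In the ranked list of both replicates, 39 peaks reached the authors' score threshold but were absent from the conservative list, which is what brought them up as a signal in data outside the comparisons. The strongest, at X 15811049 to 15811139, had a signal of 1660.07 and a replicate mean of 909 ± 118 (SD, n = 2), against a highest value of 318 among the peaks of that list that the conservative list holds. The next, at X 293305 to 293588, had a signal of 380.045 and a replicate mean of 197 ± 49.9 (SD, n = 2). Both were intergenic, with summits 6939 bp from the nearest transcript start, of Y7A5A.7, and 3787 bp from that of R57.2. Of the 39 peaks, 12 lay on V. No explanation for their absence was tested, biological or technical.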

How the results depend on the processing

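The score of 1000, the single peak per replicate pair, the lists without peaks near small RNA genes and the comparison of chromosome shares with ranked peaks were chosen after the data had been seen. No paired analysis was possible because the design has 1 group. The planned score of 830 removed no peak and is not counted below. Of 62 alternatives to the 10 results that answer a comparison, 51 kept the direction and the side of the threshold, or a count within 1.5 times. The promoter share ranged from 31.8% with 500 bp promoters to 57.2% with 2000 bp promoters and passed the test in each. The share of summits near tRNA genes ranged from 19.3% to 22.2%, and the overlap of replicate 1 with replicate 2 from 68.9% to 72.3%.

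The share of peaks on X fell to 17.2% without peaks near tRNA genes, just under the share of length, and to 18.8% without peaks near tRNA, snRNA or snoRNA genes (adjusted exact p = 0.590). By construction these settings remove the peaks near tRNA genes, of which 49.8% lay on X. The count of gene lists past the test, 7, was 3 to 5 with 1 replicate left out (3 without replicate 2, 5 without replicate 1). It was 4 at a score of 1000, 4 with the nearest transcript start, 4 with genes holding a ranked peak as background, and 2 with circular shifts. The count of motifs, 12, was 6 to 13 with 1 replicate left out (6 without replicate 2) and 6 with windows of matched GC content. The count of 6-mers, 1007, was 497 to 806 with 1 replicate left out (497 without replicate 2) and 487 with matched GC content. Leaving out a replicate meant using the list of the other alone, which held fewer peaks, 347 without replicate 2 and 676 without replicate 1. For the other changes the cause was not tested. The POU site turned from less to slightly more frequent, at 14.8% of summits against 14.4% of matched windows. That is no difference by Fisher's exact test (adjusted exact p = 0.966).

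Of 294 alternatives to single lists, motifs, 6-mers, RNA classes and the shares of peaks on V and in chromosome middles, 240 kept the call, 53 lost it and 1 turned. The chemoreceptor, B box, GAGA repeat and half-site calls passed the test in all alternatives run, 12 for the gene list and 10 for each motif, though the B box share fell to 2.49% without peaks near tRNA, snRNA or snoRNA genes. Of 12 alternatives each, the ribosomal protein call was lost in 1, the heat shock call in 2, the respiratory chain and heterochronic calls in 4 each, and the translation factor and F-box calls in 7 each. Read depth was unknown, so its limits could not be given.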

Other observations

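Of the tests below, that of the half-site as the whole cause at tRNA genes was chosen after the result had been seen. The windows of matched GC content were planned, but set against GC content as an explanation only after the half-site result had been seen. Lists without peaks near tRNA genes, used below for X and for the half-site, were added after the data had been seen. The genes in the next paragraph were chosen after their values were seen.

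Peaks lay beside some genes of the SL2 spliced leader, whose RNA is joined to downstream genes of operons, and these genes were not tested as a group. Among them were sls-2.1 (signal 189, replicate mean 95.8 ± 15.6, SD, n = 2), sls-2.4 (167, 74.8 ± 9.23), sls-2.2 (121, 60.6 ± 1.58) and sls-2.8 (89.3, 48.5 ± 4.17). The peaks at sls-2.1 and sls-2.4 are the same peaks that were assigned above to the promoters of H41C03.3 and egg-5. In all, 16 of 129 snRNA genes, the class that holds these, and 73 of 346 snoRNA genes had a summit within 500 bp. The intestinal GATA factor genes elt-2 (110.0, 55.7 ± 11.7) and elt-7 (111, 56.0 ± 42.0) were bound at their promoters, and the list of forkhead and GATA genes as a whole, with 3 of 27 bound, did not pass the test (adjusted exact p = 0.150). The bound nuclear receptor genes, 7 of 274, included nhr-68 (115), nhr-256 (79.9), nhr-35 (74.9) and nhr-69 (64.0). Actin and tubulin genes were bound at 3 of 21, with tba-2 (100.1), tbb-1 (93.8) and act-4 (62.5), at an adjusted exact p of 0.0865. No amino acid class of tRNA genes had more summits inside the gene than the others after adjustment, the smallest adjusted exact p being 0.488 for tRNA-Cys, with 7 of 13.

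The position of summits at tRNA genes may reflect reads shared between identical gene copies. Against this as the whole cause, 41 of 143 tRNA genes without an identical copy had a summit within 500 bp, 28.7% with a lower 95% limit of 21.4, while 1000 shifts of the summits gave a mean of 1.24% and at most 4.90%. Some of these summits may belong to a neighbouring tRNA gene. Only identical copies were set apart, so reads shared between nearly identical tRNA genes were not examined. A summit lay inside 21 of the 143. Of 100 such genes with no other tRNA gene within 1000 bp, 23 had a summit within 500 bp (23.0%, lower 95% limit 15.2). Among genes with an identical copy 216 of 469 had a summit within 500 bp, a higher share of 46.1% (Fisher's exact p = 0.000225, genes taken as independent), so a part played by shared reads stays open. An exact AGGTCA half-site was present at 22 of the 219 summits near tRNA genes, 10.0% with an upper 95% limit of 14.8. This is below the 96.9% of them in excess of shifts, so most of these summits lacked it. As a test of the whole cause this could not have come out otherwise, since 109 of all 1069 summits held the half-site. At those 22 summits, binding through the half-site cannot be told apart from binding by another route, since the share at the 850 other summits was 10.2% (Fisher's exact p = 1), and beyond the half-site no biological explanation was tested.

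The excess of peaks on X is consistent with the tRNA genes there, since X holds 276 of the 612 tRNA genes (45.1%) and 109 of the 219 peaks near one (49.8%). A tRNA gene on X also more often had a summit within 500 bp than one on an autosome (48.6% against 36.6%, Fisher's exact p = 0.00308). That test took genes as independent, although neighbouring tRNA genes can share a summit. Whether the tRNA genes on X differed in more than number therefore stays open. Without the peaks near tRNA genes, 17.2% of the peaks lay on X, with a 95% interval of 14.7 to 19.9 that includes the 17.7% its length gives. The condensin recruitment motif of X, TCGCGCAGGGAG with up to 2 mismatches, was present at 15 of the 255 X summits, 5.88% with an upper 95% limit of 9.52, and that motif alone falls short of the 25.9% of X peaks in excess. Beyond that motif and the tRNA genes, no biological explanation was tested.

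The higher share of half-sites at summits could come from GC content, which was higher at summits than in flanks, or from sequence inside tRNA genes. Against windows of matched GC content the half-site remained more frequent (Fisher's exact p = 3.62e-06). Without the peaks near tRNA genes it also remained more frequent than in flanks (exact McNemar p = 1.16e-05). Sequence inside tRNA genes therefore does not account for the whole difference. The matched windows all came from promoters of unbound genes, while 43.2% of the summits lay in promoters. They thus differed from the summits in region class as well as in binding, so the part played by GC content was not isolated. With 1 group the design gives no biological explanation, and none was tested.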
